A study of Mus musculus with 18 samples.

How the data were processed

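Whole-brain RNA from 18 mouse embryos at embryonic day 14.5 was sequenced, 3 brains in each of 6 groups formed by Kmt5b genotype and sex. Per the labels' protocols, brains were flash frozen, RNA was extracted with a column kit and DNase I, and libraries were made at a sequencing company; whether polyadenylated RNA was selected, and whether libraries kept strand, is not given in the sources used here. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie2 2.2.6, Cufflinks 2.2.1 and Cuffdiff were used with the mouse build mm10; their settings and the annotation are not given in the sources used here.

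The first table holds, for 25725 rows, the FPKM of each group and a lower and an upper confidence limit that the authors deposited; it has 1 value per group, so replicates had been pooled or averaged by the authors' software. The second table holds 15 comparisons between groups as the authors deposited them, each with a status, a test score, a p-value and a q-value. Of these, the 9 that change only genotype or only sex were used. The deposited q-values equal a Benjamini-Hochberg adjustment over all 216935 tests with status OK, within 5.17e-07. The authors' p-values do not go below 5e-05, which 896 tests reached, so the smallest q is 0.0121 and strong effects cannot be ranked by p. The deposited score is not standard normal: the normal quantile of p was 1.74 times the score in the median. The deposited column of log2 folds held 8058 cells spoiled by spreadsheet software and was not used. Rows that failed or exceeded the depth limit in the authors' software were left out of tests, among them Prpf8 in KO females, whose upper limit lies below its value. Row starts were counted from 0 in the table and are given here counted from 1: adding 1 gave the start in RefSeq annotation of GRCm38.p6 for 38.2% of rows with a matching symbol, against 1.88% without. Rows joining several overlapping symbols (1049) and near-identical copies, such as the globins, cannot be split between genes.

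A gene was called where the deposited q was under 0.05 and the status OK. This replaces a test on brains, which the group values do not allow: planned fits per sample, with and without the title prefix, and leaving out each brain could not be run. Folds are log2((FPKM + 1) ratio) computed from the deposited FPKM; genes at 0 in a group are listed as such. P-values over sexes were combined by Stouffer's method with the sign of the fold, and the difference between sexes was tested with a standard error taken from the fold and its p-value, both adjusted by the Benjamini-Hochberg method. The sexes share no library, but brains of different sex share title prefixes, so the 2 sexes are independent only if a prefix marks nothing. Chance values of correlations that share WT came from 200 simulations of unchanged groups, with spreads from the confidence limits divided by the square root of 3, a divisor chosen after the data were seen. On simulated data with known changes, the combined test recovered 82.4% of 68 genes changed by 0.5 log2 and 98.6% of 73 changed by 1 log2. It gave 7 false calls among 12637 unchanged genes of KO against WT. The test of the sex difference recovered 3.85%, 34.7% and 80.3% at 0.5, 1 and 2 log2, with 8 false calls among 12777 genes. Those 12777 had no planted sex difference, though some were changed alike in both sexes. These simulations used the same divisor, and their spreads may be too wide. They also held more genes that differ by sex than were called in the data, which eases the adjustment. The recovered shares may therefore not hold for the data.

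Before the data were examined, 28 gene lists were fixed, with 600 symbols of which 546 matched a row. A list's median fold was computed over members with at least 1 FPKM in any group and placed among 10000 random lists matched on mean expression in 20 bins; members of a list are expressed together, so these positions describe the list and are not p-values. A row joining several symbols was counted in a list if each of its protein-coding symbols belonged to it. That rule was set after the rows excluded by a stricter rule, and their values, had been seen, among them the row of Hoxb5 and Hoxb6; the stricter rule was run as an alternative. Genes named in the text were the target and its paralog, the 10 largest rises and falls per comparison with WT among called rows with a single symbol and at least 1 FPKM, up to 12 per genotype called in both sexes, up to 4 per list, fixed sex-linked genes and the 5 autosomal genes with the largest called fold between sexes in WT; predicted genes were passed over. The genes of KO against HET and of the sex comparison in KO, Rn45s in males, Prpf8 and Prph in KO males were named after their values had been seen. Some genes that the rule takes are not reported here. Alternatives varied the adjustment, the q and fold thresholds, the FPKM floor, the pseudocount, centring, the genes counted, the list summary and the combination method, and 5 more were added after the data were seen. No title prefix (5 in all) holds a single genotype, but within a sex any 2 genotypes share at most 1 prefix, so prefix and genotype are hard to separate within a sex. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.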

Results

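RNA was sequenced from whole brains of C57BL/6N mouse embryos at embryonic day 14.5 that carried a gene trap in Kmt5b, which encodes a methyltransferase of histone H4 lysine 20. A gene trap is an insertion that interrupts the transcript of the gene it lands in. Brains were wild type (WT), heterozygous (HET) or homozygous (KO) for the trap and of either sex, which gave 6 groups of 3 brains, 18 in all. The human cell lines that the series design also names were not analysed here. The values used are FPKM per group, so no value of a single brain enters any comparison, and the errors given are the confidence limits that the authors deposited. Summed over all rows, FPKM ranged from 471983 in WT females to 485933 in KO females; FPKM hold no read totals, so the depth is unknown. A gene is called higher or lower below where its q in the authors' deposited table of comparisons was under 0.05, and folds are differences of log2(FPKM + 1), which understate the change of weakly expressed genes. Members of gene lists are counted as table rows, since some genes have more than 1 row and some rows join several genes. No spread between brains can be set beside these folds, and what the error contains is what the authors' software estimated.

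Kmt5b, listed under its older symbol Suv420h1 (mm10 chromosome 19, 3762304 to 3818303), stepped down with the trap in both sexes. In females the deposited FPKM was 26.4 in WT (limits 21.0 to 31.8), 19.1 in HET (15.1 to 23.1) and 13.2 in KO (10.3 to 16.1). In males it was 26.9 in WT (21.3 to 32.4), 18.8 in HET (14.8 to 22.7) and 12.6 in KO (9.83 to 15.4). KO brains therefore held 50.0% of the WT value in females and 47.0% in males, and HET brains 72.4% and 69.9%. All 4 differences from WT and both differences of KO from HET were called, with q between 0.0121 and 0.0216 in the authors' deposited table. The row counts reads over the whole gene, so transcript upstream or downstream of the trap is not told apart. Kmt5c (listed as Suv420h2), the paralog with the same substrate, stood between 31.5 FPKM in WT females and 36.2 FPKM in HET females and was called in none of these comparisons. Of the 17 tested rows (16 genes) that write, erase or read H4 lysine 20 methylation, Kmt5b alone was called against WT in either genotype and sex. None of the 34 expressed genes within 1 Mb of Kmt5b was called against WT, with 0 or 1 of them at an unadjusted p under 0.05 in each comparison of the authors' deposited table.

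**Figure D1:**
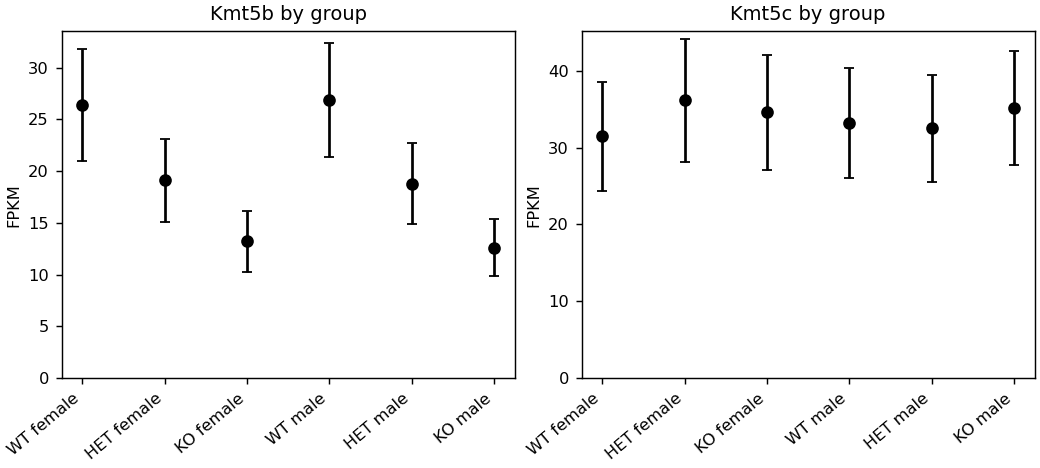
FPKM of Kmt5b (left) and Kmt5c (right) in each group; points are the authors' group values and bars their deposited confidence limits. Kmt5b goes from 26.4 to 13.2 FPKM over the female groups and from 26.9 to 12.6 FPKM over the male groups.

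In KO against WT females, 33 genes were called higher and 15 lower in the authors' deposited table. Embryonic globin genes rose, with Hbb-bh1 going from 3.73 to 14.9 FPKM, Hba-x from 251 to 706 FPKM and Hbb-y from 544 to 1294 FPKM. Choroid plexus genes rose as well, among them Ttr, the thyroid hormone carrier of that tissue, from 47.0 to 117 FPKM, Clic6 with a log2 fold of 1.01, and Kcne2 from 1.85 to 4.69 FPKM. Cmss1 (log2 fold 1.70), the ribosomal RNA row Rn45s (1.55) and Lars2, a mitochondrial leucyl-tRNA synthetase gene (0.86), also rose. Of the 10 tested blood rows 6 rose and 0 fell (9 and 0 adjusted over the list alone), and of the 10 tested choroid plexus rows 3 rose and 0 fell (8 and 0 adjusted over the list alone). Of the 20 tested meninges and fibroblast rows 3 rose and 0 fell (8 and 0 adjusted over the list alone), with Col3a1, a fibrillar collagen gene, at a log2 fold of 0.58. Apart from Kmt5b, the falls included Sla (log2 fold -0.64), Tnc (-0.61), the GABA transporter gene Slc6a11 (-0.60), the transcription factor genes Nfix (-0.59), Bhlhe22 (-0.44) and Nfib (-0.43), Tiam2 (-0.54) and Mpped1 (-0.49). No member of the synapse list was called among 30 tested (0 higher and 1 lower adjusted over the list alone), while the list median of -0.20 lay below all 10000 random lists matched on expression. Of 28 tested cell cycle rows 0 were called (2 higher and 0 lower adjusted over the list alone), with a list median of 0.18. Unadjusted p-values under 0.05 numbered 744 in the authors' deposited table, against 719.55 expected by chance. KO and WT females share 1 title prefix, held by 1 brain of each group.

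In KO against WT males, 186 genes were called higher and 15 lower in the authors' deposited table. Among the largest rises were catalytic RNAs: Rmrp, the RNA of RNase MRP, went from 2.48 to 61.4 FPKM, and Rpph1, the RNA of RNase P, from 3.61 to 47.3 FPKM. Cmss1 rose from 198 to 2354 FPKM and Lars2 from 13.3 to 84.5 FPKM, while Rn45s stood at 185 and 1816 FPKM and was not called (q = 0.999998 in the authors' deposited table). Genes of meninges and fibroblasts rose together, 12 of 20 tested with 0 falling (16 and 0 adjusted over the list alone), such as Col1a1 (log2 fold 1.59), Col3a1 (1.61) and Lum (1.75). Cartilage collagens and matrix genes rose too: Col2a1 went from 23.6 to 48.9 FPKM, Col9a1 from 0.245 to 6.13 FPKM and Matn4 from 0.195 to 4.39 FPKM, and of 10 tested rows of skeletal muscle, cartilage and skin of the head 5 rose and 0 fell (5 and 0 adjusted over the list alone). Of 11 tested choroid plexus rows 7 rose and 0 fell (8 and 0 adjusted over the list alone), with Ttr at 55.7 and 168 FPKM, and of 9 tested blood rows 5 rose and 0 fell (7 and 0 adjusted over the list alone). The falls included Neurod6 (log2 fold -0.50) and Neurod2 (-0.43), transcription factor genes of cortical excitatory neurons, Sox5 (-0.45), Tiam2 (-0.57), Mpped1 (-0.44), the planar polarity gene Celsr1 (-0.58), the transferrin receptor gene Tfrc (-0.61) and Cox7c (-0.46). Of 16 tested rows of cortical projection neurons, 1 fell and 0 rose (3 and 0 adjusted over the list alone), and the list median of -0.21 lay below all random lists; in KO females 1 of these rows fell and in HET females 0 (3 and 4 adjusted over the list alone), with medians of -0.15 and -0.13. By the sample titles, KO and WT males share no title prefix; whether a prefix marks a litter is not given in the sources used here.

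In HET against WT females, 107 genes were called higher and 30 lower in the authors' deposited table. Ttr rose from 47.0 to 239 FPKM, and 8 of 11 tested choroid plexus rows rose with 0 falling (10 and 0 adjusted over the list alone), including Kcne2 (log2 fold 1.77), Clic6 (1.67) and the water channel gene Aqp1 (1.36). Of 20 tested meninges and fibroblast rows 11 rose and 0 fell (16 and 0 adjusted over the list alone), and of 9 tested blood rows 5 rose and 0 fell (9 and 0 adjusted over the list alone) with Hbb-bh1 at 3.73 and 21.5 FPKM and Hba-x at 251 and 771 FPKM. The falls included the glutamate receptor genes Grm5 (log2 fold -0.65) and Grin2b (-0.47), the GABA receptor gene Gabbr2 (-0.53), the scaffold gene Dlg2 (-0.50), Slc6a11 (-0.69), Olig1 (-0.66) and Tnc (-0.52). Of 30 tested synapse rows 2 fell and 0 rose (9 and 0 adjusted over the list alone), with a list median of -0.24. Of 28 tested cell cycle rows (27 genes) 1 rose, the row of Ccnd1, and 0 fell (11 and 0 adjusted over the list alone), with a list median of 0.27. Prph (log2 fold -0.61), the gene of a peripheral neuron filament, fell. HET and WT females share no title prefix.

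In HET against WT males, 85 genes were called higher and 6 lower in the authors' deposited table. Ttr had the largest rise among called single-gene rows of at least 1 FPKM, from 55.7 to 229 FPKM, with Aqp1, Kcne2 and Clic6 at log2 folds of 1.33, 1.33 and 1.29. Of 11 tested choroid plexus rows 7 rose and 0 fell (8 and 0 adjusted over the list alone), and of 20 tested meninges and fibroblast rows 10 rose and 0 fell (11 and 0 adjusted over the list alone), including Col1a1 (1.38) and Lum (1.44). Of 9 tested blood rows 4 rose and 0 fell (7 and 0 adjusted over the list alone). Apart from Kmt5b, the 5 other falls were all Hox genes, which pattern the hindbrain and spinal cord: the row joining Hoxb5, Hoxb5os and Hoxb6 went from 38.3 to 11.5 FPKM, Hoxc4 from 13.1 to 5.73 FPKM and Hoxc5 from 4.70 to 1.60 FPKM. Of 12 tested Hox rows 5 fell and 0 rose (7 and 0 adjusted over the list alone), and the list median was -0.99. In KO females, KO males and HET females no Hox row was called (0, 1 and 0 higher and 0 lower adjusted over the list alone), and the medians were 0.21, -0.17 and -0.03. No gene of the synapse, cell cycle or cortical projection neuron lists was called, with 0 adjusted over the list alone in each. HET and WT males share 1 title prefix, held by 1 brain of each group. Fewer tests than chance would give reached an unadjusted p under 0.05 in the authors' deposited table, 455 against 718.2 expected; in KO males there were 1099 against 727.4 and in HET females 1317 against 722.55.

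**Figure D2:**
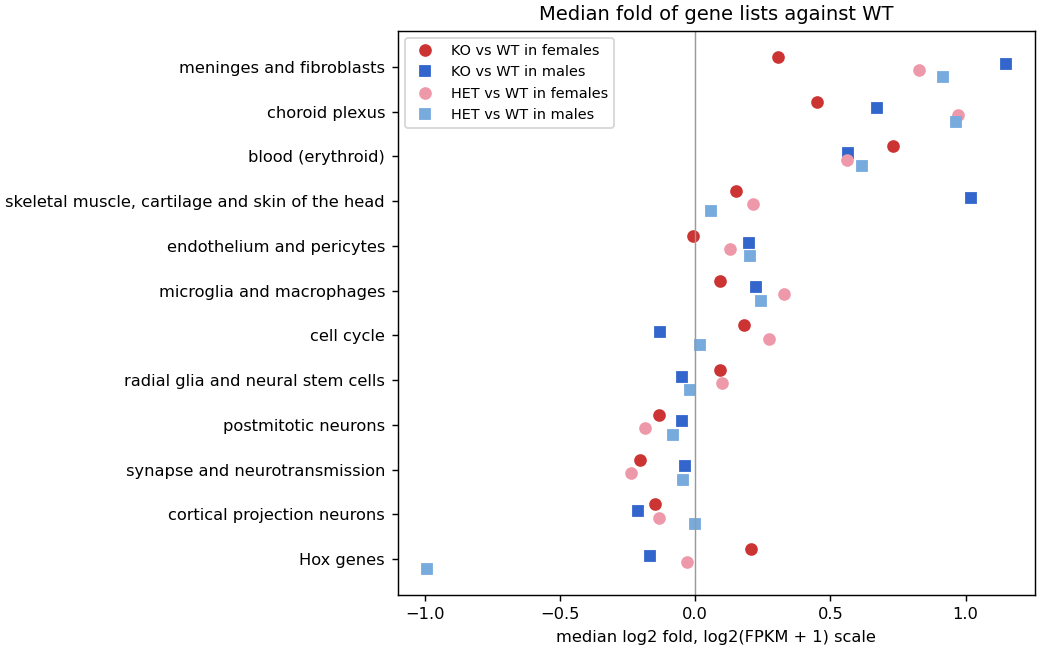
Median log2 fold against WT, on the log2(FPKM + 1) scale, of the members of 12 gene lists with at least 1 FPKM in any group, with a colour for each comparison. The meninges list lies at 0.31, 1.15, 0.83 and 0.92 in KO females, KO males, HET females and HET males, and the synapse list at -0.20, -0.04, -0.24 and -0.05.

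Calls overlapped between the sexes more than independent lists would. In KO, 22 genes were higher in both sexes against 0.368 expected from independent lists, and Mpped1, Tiam2 and Kmt5b were lower in both. In HET, 63 genes were higher in both sexes against 0.640 expected, and Kmt5b alone was lower in both. Members of the same tissue list, such as Ttr, Clic6 and Kcne2, are among the shared genes of both genotypes. Such genes are expressed together, so the excess over the expected count does not measure how many genes repeat independently. Log2 folds across 12988 genes correlated between the sexes with a Spearman rho of 0.32 in KO, and with 0.33 across 12919 genes in HET; genes are not independent replicates. KO females and HET males, which share no library in their comparisons with WT, gave a rho of 0.25, and HET females and KO males 0.28; brains of different sexes do share title prefixes, so these comparisons are independent of each other only if a prefix marks nothing. Within a sex, KO and HET folds share the WT group: their rho was 0.79 in females and 0.60 in males, beside 0.47 and 0.46 in simulated unchanged groups. The covariance within a sex was 0.0252 in females and 0.0200 in males, below the simulated 0.0363 and 0.0367. The simulated spreads thus seem wider than those of the data, and the simulated rho is a poor reference. No shared effect of KO and HET within a sex can be read from either value. With group values only, the WT groups could not be divided. When the p-values of the authors' deposited table were combined over the sexes by Stouffer's method, 247 genes were higher and 48 lower in KO, and 264 higher and 21 lower in HET. A direct test of the difference between sexes found 2 genes for KO and 1 for HET past an adjusted threshold of 0.05, Tfrc and Hbb-b2, with 368 and 256 genes at an unadjusted p under 0.05. Its error comes from deposited p-values that do not go below 5e-05. A gene with folds of the same sign in both sexes therefore cannot reach a smaller p, which does not pass the adjustment with so few calls. Tfrc and Hbb-b2 had folds of opposite sign, and the small count says little about genes that moved the same way by unlike amounts. With standard errors from the confidence limits, also planned beforehand, 0 of these calls were kept: adjusted p was 0.325 for Tfrc in KO, and for Hbb-b2 it was 0.999966 in KO and 0.0883 in HET. Those errors are wider than the simulated spreads above, which already seemed too wide over all genes. They passed 3 other rows in KO: Lars2 (adjusted p 0.00596, against 0.999996 by the first test), Lect1 (0.0169 against 0.118) and 1 row without a symbol. In simulated data the first test recovered 34.7% of genes changed by 1 log2 in males alone. Those data held many more genes that differ by sex than were called here, which eases the adjustment, so this share may not hold here. Calls made in one sex alone do not show a difference between the sexes, and few calls of the direct test do not show that the sexes are alike.

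**Figure D3:**
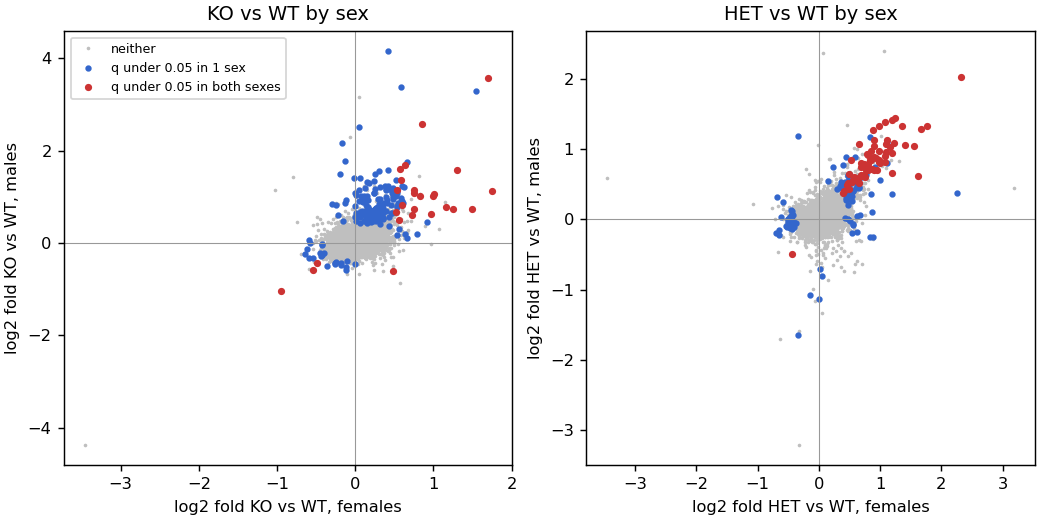
Log2 fold against WT in females (horizontal axis) and males (vertical axis) for genes with at least 1 FPKM in any group, KO left and HET right; red marks genes with q under 0.05 in both sexes and blue those in 1 sex. Red points lie mostly in the upper right, where 22 genes in KO and 63 in HET were higher in both sexes.

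Between KO and HET females 8 genes were higher and 33 lower in KO, in the authors' deposited table. Of 11 tested choroid plexus rows 5 fell and 0 rose (6 and 0 adjusted over the list alone), and of 19 tested meninges and fibroblast rows 8 fell and 0 rose (13 and 0 adjusted over the list alone), with Ttr at 239 FPKM in HET and 117 in KO. Between KO and HET males 38 genes were higher and 12 lower in KO, in the authors' deposited table. Hox genes stood higher in KO, with 5 of 13 tested rising and 0 falling (6 and 0 adjusted over the list alone), as did cartilage genes such as Col2a1 and the structural RNA Rpph1. Neurod6 fell in KO against HET males, as did Tiam2, Mpped1 and Sox5.

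Sex was compared within each genotype. In WT, 4 genes were higher and 6 lower in males in the authors' deposited table, in HET 5 and 9, and in KO 66 and 6. With the adjustment made within each comparison, 0 of the calls in WT and 0 of those in HET were left. The authors' p-values do not go below 5e-05, so calls as few as these could not pass that adjustment, whatever the size of the difference. Xist, the RNA that silences an X chromosome in females, stood at 37.4 FPKM in WT females and 0.0132 FPKM in WT males, and was called in each genotype. The Y-linked Uty was listed at 0 in all female groups and at 4.95 FPKM in WT males, and was called. Eif2s3y (0.0201 and 24.1 FPKM), Ddx3y (0.00755 and 9.51 FPKM) and Kdm5d (0.00278 and 8.84 FPKM) were not called between WT females and WT males in the authors' deposited table, although they were called in HET, where females were listed at 0. A gene that lies just above 0 in a group can thus go uncalled at a difference of this size. In WT the autosomal calls were Hbb-b2 and Tfrc, the rows joining Gm15446 with Zfp932 and Hoxb5 with Hoxb6, and Dynlt1b. In KO the genes higher in males included Col9a1, Col2a1, Col1a1, Rmrp and Rpph1, which also rose in KO against WT males.

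**Figure D4:**
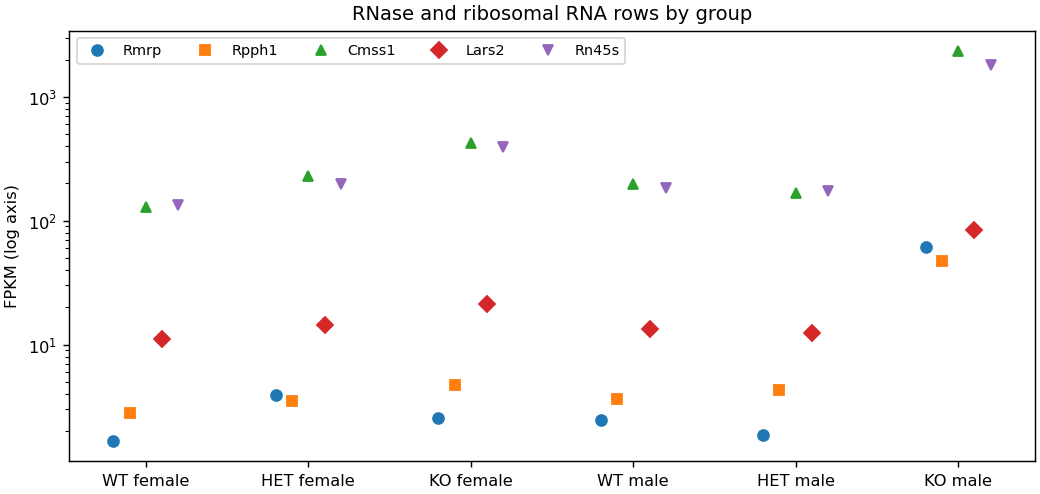
FPKM (log axis) of Rmrp, Rpph1, Cmss1, Lars2 and Rn45s in each group; points are the authors' group values, drawn without limits. All 5 are highest in KO males, with Rmrp at 61.4 FPKM against 2.48 FPKM in WT males, and Rn45s at 392 FPKM in KO females against 133 FPKM in WT females.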

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

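The tests in this part were planned, except for 1 error named below as chosen after the data were seen. Both genes below passed the planned test of the difference between sexes in the response to the trap, but neither passed it with standard errors from the confidence limits, also planned beforehand. Tfrc, the transferrin receptor gene, was called in opposite directions in KO: its log2 fold was 0.48 in females and -0.61 in males, a difference of -1.09, and WT females (15.6 FPKM) and WT males (24.9 FPKM) already differed while the KO groups stood at 22.3 and 16.0 FPKM. Hbb-b2 is an adult globin row that shares near-identical sequence with other globin rows. Its log2 fold was larger in males than in females by 1.15 in KO and 1.52 in HET. It stood at 202 FPKM in WT females and 79.7 FPKM in WT males, and at 164 and 144 FPKM in KO females and males. Both differences of Hbb-b2 use the same WT groups, which already differed, so they are not independent of each other. The adjusted p of the test of the difference was 1.58e-04 for Tfrc in KO, 0.0358 for Hbb-b2 in KO and 0.0350 for Hbb-b2 in HET; with the alternative errors it was 0.325, 0.999966 and 0.0883, and with those divided by the square root of 3, chosen after the data were seen, 5.24e-08, 3.45e-05 and 3.21e-10. Whether these calls stand thus turns on the error model. Errors from the undivided limits are wider than the simulated spreads, which already seemed wider than those of the data over all genes. That does not settle the error of either single gene. No explanation was tested for either gene.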

How the results depend on the processing

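Alternatives named here as added were chosen only after the results were seen; all others were planned. No gene kept a deposited q under 0.01 in any of the 9 comparisons (0 in each), which follows from the smallest possible q of 0.0121. Adjusting within the comparison, with or without a floor of 1 FPKM, left 0 calls between sexes in WT and 0 in HET. Since p does not go below 5e-05, so few calls could hardly pass that adjustment, whatever their size. Counts against WT stayed within 1.5 times. Without joined rows, predicted genes and sex chromosomes, 3 calls were left between sexes in WT and 6 in HET, fewer genes being counted. Added after the data were seen, leaving out 8 lists of non-neural tissue left 27 of 41 calls for KO against HET females, and leaving out rows at exactly 0 left 9 of 14 between sexes in HET. The test of the sex difference, 2 genes in KO and 1 in HET, gave 3 and 0 with standard errors from the confidence limits, and 0 of the genes in either genotype were shared, so none of those calls was kept; Lars2, Lect1 and 1 row without a symbol were called instead. With those divided by the square root of 3, chosen after the data were seen, it gave 40 and 11, with the 2 and the 1 all kept. The planned test can hardly call genes whose folds have the same sign in both sexes, as said above. The cause was otherwise not tested, and the planned counts are the ones reported. At an FPKM floor of 10, rho moved to 0.28 for KO between sexes, to 0.21 for HET females against KO males, to 0.81 for KO against HET in females and to 0.54 in males; at a floor of 0.1 it moved to 0.30 for HET between sexes, 0.23 for KO females against HET males and 0.74 for KO against HET in females. The cause of these shifts was not tested. Combining p-values by Fisher's method gave 243 genes in KO and 224 in HET against 295 and 285. Of the list medians under all alternatives, 737 kept their side of the random lists, 14 lost and 28 gained it, and 17 others moved across 0 without being outside at first; no median outside the random lists changed sign. Leaving out each brain, fits per sample and a title prefix term were not run, since the tables hold group values. No paired analysis was possible because the columns carry no replicate. How far 1 brain decides any call is therefore unknown.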

Other observations

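All tests of explanations here were chosen after the results had been seen. Several gene groups outside the comparisons above moved or stood still. In HET males caudal genes beyond the called Hox rows also had low values: Hoxb8 had a log2 fold of -3.21 and stood at 0.401 FPKM, and Hoxb7 stood at 0.155 FPKM against 2.48 in WT males, neither called in the authors' deposited table, and the midbrain and hindbrain list had a median of -0.09 with 0 of 24 called (0 higher and 2 lower adjusted over the list alone), Pax2 at -0.44 and Tlx3 at -0.63 log2. Prph, which fell in HET females, rose in KO males (log2 fold 0.59). Imprinted genes had 2 called higher in each comparison with WT (5, 3, 4 and 2 adjusted over the list alone in KO females, KO males, HET females and HET males), Igf2 among them at 0.59 to 1.36 log2, and Igf2 is also in the meninges list. Of the endothelium and pericyte list 0, 2, 2 and 1 members rose in KO females, KO males, HET females and HET males, and of the microglia and macrophage list 0, 2, 2 and 1; adjusted over the list alone these were 0, 4, 3 and 4, and 2, 4, 6 and 3.

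Other lists held few or no calls against WT, but some lay as far out among the random lists as those above. Ribosomal protein genes lay at percentile 99.99 or above and Wnt pathway genes at 99.76 or above in every comparison with WT. Postmitotic neurons lay at percentile 0 in KO females, HET females and HET males. Intermediate progenitors lay at 100 in KO females and 99.97 in HET females. Tnc (radial glia list) and Bhlhe22 (postmitotic neurons) fell in KO and HET females, Neurod2 and Neurod6 (postmitotic neurons) and Cox7c (oxidative phosphorylation) fell in KO males, and of the oligodendrocyte and astrocyte list Gja1 rose in KO males and in HET of both sexes, Sox10 rose in KO males and Olig1 fell in HET females. Adjusted over the list alone, the oligodendrocyte and astrocyte list had 0, 4, 1 and 1 higher and 1, 0, 2 and 0 lower in KO females, KO males, HET females and HET males, radial glia had 2, 0, 1 and 0 higher and 1, 0, 1 and 0 lower, and postmitotic neurons had 2, 2, 2 and 0 lower. The Wnt list had 3 higher in HET females, the stress list 1 higher in KO males, and the eye list 1 higher and 1 lower in KO females and in HET females, on the same adjustment. In order of KO females, KO males, HET females and HET males, list medians in log2 were 0.09, -0.05, 0.10 and -0.02 for radial glia, 0.16, -0.04, 0.15 and 0.03 for intermediate progenitors, -0.13, -0.05, -0.19 and -0.08 for postmitotic neurons and 0.02, -0.08, -0.03 and -0.03 for GABAergic neurons. They were -0.03, 0.08, -0.10 and -0.03 for oligodendrocyte and astrocyte genes, 0.00, 0.02, 0.07 and 0.03 for p53 targets, 0.11, 0.11, 0.11 and 0.07 for Wnt pathway genes and -0.01, 0.17, -0.03 and 0.06 for immediate early and stress genes. Cytosolic ribosomal protein genes had 0.12, 0.02, 0.10 and 0.06, oxidative phosphorylation genes -0.02, -0.09, 0.01 and -0.01, and clustered protocadherins -0.12, -0.03, -0.20 and -0.08. Eye and lens genes had 0.01, 0.03, 0.08 and 0.12, pituitary and hypothalamus genes 0.10, -0.03, 0.14 and -0.03, and sex-linked genes -0.01, -0.07, -0.01 and -0.05. Nnt, which separates C57BL/6 substrains, lay between 15.4 and 17.0 FPKM in all groups.

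The meninges, choroid plexus and blood lists had medians above all random lists in every comparison with WT, though in KO females 3 of 20 meninges and 3 of 10 choroid plexus rows were called. A lower share of neural tissue alone was taken to raise all non-neural lists alike, but in KO males the meninges list lay 0.95 log2 above the endothelium list (permutation test of list membership, p = 8e-05, or 0.00192 corrected for 24 pairs). Genes of a list are not independent, so this p is too small. The endothelium list was the lower one of the pair in each comparison with WT. Vessels also run within neural tissue, so their genes could fall with the neural share. The gap therefore does not decide against a lower neural share. A response graded with Kmt5b copies in both sexes, acting alone, is argued against by KO against HET females. Medians there were -0.58 log2 for the choroid plexus list and -0.54 for meninges. In males these were -0.18 and 0.22, so the meninges list there went the graded way. Unlike amounts of tissue left on the brains of KO and HET females could hide a graded response, so it is not excluded. Tissue left on some brains at dissection may contribute: the list of head muscle, cartilage and skin had a median of 1.02 in KO males, but of 0.15 in KO females, 0.22 in HET females and 0.06 in HET males, where the meninges median was still 0.92. In each of KO females, HET females and HET males 1 row of the head list was called higher and 0 lower (2 and 0 adjusted over the list alone). Group values cannot show whether 1 brain or all 3 carried such tissue, so it cannot be told apart from an effect of genotype, which stays open.

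Rmrp, Rpph1, Cmss1 and Lars2 rose in KO males. Reads of ribosomal RNA counted at Cmss1 are a candidate explanation for that row. Cmss1 over Rn45s varied by 1.37 times over the groups while Rn45s varied by 13.6 times. Lars2 over Rn45s went from 0.0839 in WT females to 0.0465 in KO males. The groups nevertheless ranked in the same order by Lars2 as by Rn45s. A ratio also falls if a row holds reads of its own beside such reads. The ratio therefore does not decide against that explanation for Lars2. More non-polyadenylated RNA in the KO male libraries may account for Rmrp and Rpph1. Replication-dependent histones had a median of 0.40 log2, but also 0.24 in KO females, 0.20 in HET females and 0.13 in HET males, with 0 called. For 5 other small structural RNAs the median was 0 in KO males, with 1 row above 0, and 0.43 in KO females, with 3 above 0. A median of exactly 0 comes from a row with the same value in both groups. With 5 rows it says little for or against this explanation. Loss of Kmt5b itself remains open, because the fold of Rmrp was 3.75 log2 larger in males than in females and whether that passes turns on the error model: the adjusted p was 0.847 by the planned test, 0.999966 with errors from the confidence limits and 1.02e-04 with those divided by the square root of 3, chosen after the data were seen (0.999996, 0.00596 and 1.21e-13 for Lars2, 1.71 log2 larger in males). Both genes had folds above 0 in both sexes, though Rmrp was not called in KO females (log2 fold 0.42). Deposited p does not go below 5e-05. With so few calls the planned test could therefore not pass them, and its p-values decide nothing here. These explanations cannot be told apart for Rmrp and Rpph1 without values per brain.

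Embryonic globins rose in HET and KO females, and the synapse list had medians of -0.24 and -0.20, with 2 and 0 of 30 called lower. In HET males the synapse median of -0.05 also lay low among the random lists, at percentile 0.59. In KO males it was -0.04, at percentile 74.3. Embryonic globins rose in males too, by less. Hba-x and Hbb-y were called at log2 folds of 0.73 and 0.74 in KO males and 0.62 and 0.66 in HET males. Hbb-bh1 was called in KO males (1.12) but not in HET males (0.38). More blood alone would raise all globins by the same factor, but 3 embryonic rows exceeded 3 adult ones (Hba-a1 with Hba-a2 in a pair of rows, Hbb-b1 with Hbb-bs) by 1.30 log2 in HET and 0.95 in KO females, or by 1.49 and 1.16 with Hbb-b2, included after the data were seen, which stood at -0.34 and -0.30. Dilution of all neural genes by other tissue would lower neural lists alike, but the radial glia list lay 0.34 log2 above the synapse list in HET females and 0.30 in KO females (permutation tests of list membership, p = 2e-05 and 4e-05, which are too small since genes of a list are not independent), and its own medians were 0.10 and 0.09. That list is not purely neural, since Sox9 is also in the head tissue list, so added tissue could open part of the gap. The intermediate progenitor list, at 0.15 in HET and 0.16 in KO females, did not fall either. An earlier developmental stage of the HET and KO female brains relative to WT females would go with the cell cycle medians of 0.27 log2 in HET and 0.18 in KO females. The synapse medians go the same way but belong to the pattern to be explained, so they add no support. In KO males, however, embryonic globins also exceeded adult ones, by 0.38 (0.29 with Hbb-b2), with a cell cycle median of -0.13. In HET males the globin difference was -0.23 (-0.33 with Hbb-b2). Calls seen before the test helped to form that hypothesis; HET and WT females share no title prefix, and a stage difference between litters may give the same values as an effect of genotype, which also stays open.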
